A study of Oryctolagus cuniculus with 11 samples.

How the data were processed

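The series holds single-cell RNA libraries of ventral ganglionic eminence, the embryonic and neonatal source of cortical interneurons, dissected from the brains of rabbit kits and dissociated with a neural tissue kit. Per the labels the libraries were made with 10x Genomics droplets, and the cell type is given as interneuron. Kits with intraventricular haemorrhage (IVH) of moderate grade received an adenovirus that carries GFP (Ad-GFP) or sonic hedgehog (Ad-SHH) under a CMV promoter, injected into the cerebral ventricle. The titles carry a number that is used here to name each library within its group (no IVH K226 and K231, IVH K231 and K232, Ad-GFP and Ad-SHH 251, 253 and 254). The labels give day 3 for the libraries with and without IVH and give no day for the Ad libraries. The library labelled control, of which 16839 cell barcodes were counted, was not analysed here because no matrix of counts was used for it.

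The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, as whole numbers. The authors counted with Cell Ranger 6.0.1 against the build OryCun2.0, per the submitters' processing notes; annotation and intron counting are not stated there. Genes are given by symbol alone, so no coordinates are printed. The matrices of the 6 Ad libraries also hold counts of 12 multiplexing tags, which were left out of every sum of genes. No feature carries the symbols NKX2-1, DLX2, CCND1, NKX2-2, MAF, NOTCH1, HES5 or TREM2, so these genes were not analysed here.

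Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from 13 mitochondrial genes. Scrublet scores were computed per library in scanpy 1.11.5. Its automatic threshold called under 0.5% of cells in 6 of the 10 libraries, so the 6% of cells with the highest scores in each library were removed instead, a rule chosen after seeing the data. The 4 libraries with and without IVH and the 6 Ad libraries were clustered as separate series. Each used 2000 highly variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 with seed 1. Variable genes were chosen with the library as batch, and each gene was centred on its mean within each library before the components were computed. No other batch correction was made. Each cluster was named from 22 marker lists, and names end in "-like" because they rest on markers alone. The tools were Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

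UMI counts were summed per library over all kept cells and over each class with at least 30 cells in every library of a comparison, since libraries and not cells are replicates. The sums were tested in R 4.3.3 with the robust quasi-likelihood test of edgeR 4.0.16 after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment within each fit and a threshold of 0.05. Each log2 fold change is given with a standard error (SE), the fold divided by the root of its F statistic. Levels are CPM over the gene UMIs of the sum, without TMM factors. IVH was compared with no IVH (2 libraries against 2), and Ad-SHH with Ad-GFP (3 against 3), each on its own libraries. The difference of effect between a neuron and a progenitor class was tested with limma 3.58.1 on the per-library difference of log2 CPM (prior count 2) between MGE interneuron-like and GE intermediate progenitor-like cells, where MGE, CGE and LGE are the medial, caudal and lateral ganglionic eminences (GE).

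The 21 gene lists were Hedgehog pathway components, Hedgehog transcriptional targets, MGE interneuron transcription factors, interneuron identity and migration, neurogenesis transcription factors of other lineages, neuronal maturation and synapse, cell cycle, Notch signalling, interferon response, inflammatory cytokines and NF-kappaB, haem and iron handling, oxidative stress response, hypoxia and glycolysis, p53 and apoptosis, reactive astrocyte, activated and phagocytic microglia, homeostatic microglia, oligodendrocyte lineage and myelin, dissociation and immediate early genes, blood and erythroid, and oxidative phosphorylation. The list of MGE interneuron transcription factors is not restricted to the MGE. It also holds NR2F1, NR2F2, SP8, SP9 and PROX1, which are on the marker list of CGE or LGE interneurons. The lists were tested with camera in limma at a preset correlation of 0.01 and adjusted over lists within each fit, with an estimated correlation and fry beside it. Members were also adjusted over the list alone where at least 3 were measured. The sets of genes changed by IVH were tested in the class of the same name in the Ad comparison. The series were clustered apart, so classes were matched between them by name alone, here and in the fit of 10 libraries described below.

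Shares of cells per class were compared between groups with an exact two-sided permutation test of the difference of means, for which the smallest possible p is 0.333 with 2 libraries against 2 and 0.1 with 3 against 3. Neither can pass 0.05. Shares of single libraries carry 95% exact (Clopper-Pearson) intervals, which cover counting error only. Cells were also counted per class and tested with edgeR.

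The genes named in the text follow a rule. In every comparison SHH, PTCH1, GLI1, HHIP, NKX2-1, LHX6, DLX1, DLX2, SST and GAD1 are given where measured, whatever their test. The 8 higher and 8 lower genes with the smallest p among those that pass in all cells follow, then the 3 higher and 3 lower in each class, then up to 4 passing members of each list with the largest fold. Where fewer than 5 genes pass in a fit, the 5 with the smallest p may be given as not passing. Genes outside the rule, named because a fit with a block or a level in 1 library singled them out, were chosen after their values were seen. The groups, comparisons, tests, gene lists, cell markers, naming rule and the first set of alternative settings were fixed before the data were examined.

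This first set was RLE scaling, DESeq2 1.42.0, no filter on low counts, doublets kept, a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), resolution 0.5, the removal of each library in turn, a fit of the 10 libraries in 4 groups, a prior count of 0.5, the 100 genes with the smallest p as sets, edgeR on cell counts, and the title number as a block. Alternatives chosen after seeing the data were the removal of both libraries numbered 254, sums without choroid plexus-like cells, shares among the 5 neuron and progenitor classes alone, an estimated correlation and fry for the IVH gene sets, and the block in the class difference. For values without a call, such as shares, a change of sign was counted as a moved value.

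The title numbers 251, 253 and 254 each occur once with Ad-GFP and once with Ad-SHH, and the labels do not say what they mark. Over all genes tested in all cells, after removal of group means, libraries with the same number correlated at 0.145, 0.440 and 0.215, and libraries with different numbers at -0.287 to 0.100. Ad libraries with the same number shared 0 cell barcodes, and any other pair of the 10 libraries shared 5 to 30, with 15 between the libraries numbered K231. The numbers therefore pair the Ad libraries, and values with the number as a block stand beside the results they change. No paired analysis was possible because only the number K231 occurs both with and without IVH.

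The procedure was tested on simulated data with the levels and spread of these libraries, in which 200 genes were changed, 100 of them at each fold, less any that the filter removed. The changed genes were drawn from those with a mean above 20 UMIs per library, so recovery of genes with fewer UMIs was not tested. In IVH against no IVH, edgeR recovered 11% of the genes changed by 1 log2 unit and 74% of those changed by 2 in all cells, with 2 false calls. It recovered 46% and 93% in cycling progenitor-like cells (13 false), 37% and 88% in GE intermediate progenitor-like cells (9 false), and 40% and 95% in MGE interneuron-like cells (8 false). DESeq2 recovered 33% and 83% in all cells with 33 false calls. In Ad-SHH against Ad-GFP, edgeR recovered 42% and 90.9% in all cells (6 false), 66% and 93% in cycling progenitor-like cells (19 false), 77% and 99.0% in GE intermediate progenitor-like cells (20 false), and 82% and 99% in MGE interneuron-like cells (10 false). DESeq2 recovered 65% and 94.9% in all cells with 41 false calls, and edgeR with the block 29% and 87.9% with 5. The class difference recovered 0 of 100 and 22 of 98 genes with IVH and 13 of 96 and 89 of 98 with Ad-SHH. For a list of genes raised by 1 log2 unit, camera gave p values from 3.96e-67 to 2.32e-25. The estimated correlation gave 4.52e-05 to 0.0428, and 0.00415 to 0.0428 in IVH against no IVH alone. These p values were not adjusted over lists, unlike those of the real lists. The smallest camera p of an unchanged list was 0.240. Genes were drawn independently of each other, so the unchanged lists cannot show false calls that come from correlated genes. The simulated data also held no effect shared by the libraries of a title number or by the classes of a library.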

Results

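Single-cell RNA counts were analysed for 10 libraries of rabbit ventral ganglionic eminence in 4 groups: 2 without IVH, 2 with IVH, 3 with IVH and Ad-GFP, and 3 with IVH and Ad-SHH. Without IVH, the libraries K226 and K231 held 47298664 and 44505765 gene UMIs over 11110 and 8551 barcodes. With IVH, the libraries K231 and K232 held 48506611 and 49416767 UMIs over 9108 and 10611 barcodes. The Ad-GFP libraries 251, 253 and 254 held 45187453, 55345763 and 38391101 UMIs over 6312, 5762 and 6405 barcodes, and the Ad-SHH libraries of the same numbers held 68457632, 47806627 and 42301519 over 7861, 4440 and 5794. After the cell filter and removal of doublets, 8113, 6377, 6945, 9028, 5491, 4566, 5394, 6095, 3235 and 4847 cells were kept in this order of libraries. The cells formed interneuron-like, striatal projection neuron-like, progenitor-like, glial, microglial, vascular, ependymal-like and choroid plexus-like classes, of which 13 in each comparison held enough cells to be tested. Fold changes are log2 values ± SE with n = 2 and 2 libraries for IVH and n = 3 and 3 for Ad-SHH.

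The comparison of IVH with no IVH asks how progenitors, interneurons and their transcription factors differ at day 3 in kits with a haemorrhage. PSMB9, an interferon-inducible proteasome subunit, rose in cycling progenitor-like cells (2.86 ± 0.27, adjusted p = 1.79e-04), in ependymal-like cells (2.27 ± 0.25, adjusted p = 7.78e-04) and in astroglia-like cells (2.38 ± 0.22, adjusted p = 0.0206). HMOX1, which degrades haem, rose in endothelial-like cells (3.25 ± 0.44, adjusted p = 0.0482) and in GE intermediate progenitor-like cells (3.06 ± 0.42, adjusted p = 0.0219). RNA of GFAP, the filament protein of reactive astrocytes, went from 2.89 and 1.59 CPM to 20.5 and 36.4 CPM in GE intermediate progenitor-like cells (3.87 ± 0.49, adjusted p = 0.0192), and from 64.5 and 29.6 CPM to 125 and 179 CPM in all cells. This call ended at resolution 0.5 (3.32, adjusted p = 0.801; 6.34e-13 to 0.801 over the alternatives). In MGE interneuron-like cells LHX6, the transcription factor that marks MGE interneurons, stood at 223 and 311 CPM without and 243 and 260.2 CPM with IVH (-0.03 ± 0.21, adjusted p = 0.999).

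Summed over 13 classes, edgeR called 91 gene changes, 87 higher and 4 lower. Leaving out 1 library at a time gave 370 (no IVH K226), 2190 (no IVH K231), 390 (IVH K231) and 81 (IVH K232). In all cells edgeR called 0 of 15134 genes, with 1018 at an unadjusted p under 0.05 and 209 called by DESeq2; without no IVH K226 it called 62 and without no IVH K231 it called 809. The genes with the smallest p in all cells did not pass: HMOX1 (4.38 ± 0.34, adjusted p = 0.177), the fatty acid carrier FABP4 (4.13 ± 0.30, adjusted p = 0.177), the mRNA decapping enzyme DCPS (4.27 ± 0.39), PSMB9 (1.91 ± 0.18) and the lysosomal protease CTSD (2.11 ± 0.20). Microglia-like cells had 0 of 9787 genes called by edgeR, with 650 at an unadjusted p under 0.05 and 25 by DESeq2. In cycling oligodendrocyte precursor-like and mural-like cells both tools called 0 genes, with 259 and 146 at an unadjusted edgeR p under 0.05.

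Cycling progenitor-like cells held 53 of the 91 calls, 52 of them higher. The thyroid hormone binding protein CRYM (1.75 ± 0.17, adjusted p = 1.79e-04), the matrix protein SPARC (1.82 ± 0.20, adjusted p = 7.35e-04), the secreted phosphoprotein SPP1 (2.53 ± 0.33, adjusted p = 0.00227), the immediate early gene FOSB (1.51 ± 0.20, adjusted p = 0.00238) and the hyaluronan receptor CD44 (2.18 ± 0.41, adjusted p = 0.0242) rose. ECEL1, an endopeptidase of neurons, fell from 13.1 and 14.8 CPM to 3.50 and 1.65 CPM (-2.37 ± 0.41, adjusted p = 0.0147). The GABAergic determinant DLX1, at -0.30 ± 0.19, did not pass. PSMB9 and FOSB passed under each of the 11 alternatives, with highest adjusted p of 3.99e-04 and 0.0105. FOSB is on the list of dissociation and immediate early genes, which passed upward with camera in 5 of 14 fits. Without IVH K232 the calls of CD44 (adjusted p = 0.279; 1.30e-04 to 0.462 over the alternatives) and ECEL1 (adjusted p = 0.186; 1.99e-06 to 0.186) ended. SPARC and SPP1 fell short in the fit of 10 libraries (adjusted p = 0.0548 and 0.796). CRYM fell short with doublets kept, at 0.86 (adjusted p = 0.0699; 1.17e-18 to 0.634 over the alternatives).

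In ependymal-like cells HOPX, a homeodomain protein of radial glia, rose from 87.7 and 57.7 CPM to 449.8 and 323 CPM (2.53 ± 0.25, adjusted p = 3.40e-04). The neuropeptide gene HCRT rose there as well (2.86 ± 0.33, adjusted p = 0.00108), but its call ended in the fit of 10 libraries (2.84, edgeR adjusted p = 0.898). In astroglia-like cells the transcription factor CEBPD rose from 156 and 145 CPM to 578 and 579 CPM (2.12 ± 0.19, adjusted p = 0.0206). This call ended without no IVH K226 (adjusted p = 0.195), no IVH K231 (0.0701) or IVH K232 (0.116), within a range of 1.38e-19 to 0.195 over the alternatives. That of PSMB9 in astroglia-like cells ended without no IVH K226 (adjusted p = 0.0676) or IVH K232 (0.177), in a range of 4.67e-15 to 0.177. DCPS rose in 7 classes, with 4.06 ± 0.34 in CGE or LGE interneuron-like cells (adjusted p = 3.05e-04), 3.65 ± 0.45 in MGE interneuron-like cells (adjusted p = 0.00673) and 4.32 ± 0.42 in striatal projection neuron-like cells (adjusted p = 0.00468). In astroglia-like cells (4.15 ± 0.41, adjusted p = 0.0250) and oligodendrocyte precursor-like cells (4.27 ± 0.43, adjusted p = 0.00256) its call ended without IVH K232 (0.144 and 0.0828), and in the former also without no IVH K226 (0.226) or no IVH K231 (0.0869). Over the alternatives the adjusted p ran from 8.30e-16 to 0.506 and from 9.65e-21 to 1.00. In GE intermediate progenitor-like cells DCPS stood at 5.48 ± 0.61 (adjusted p = 0.0219), a call that ended with the stricter cell filter (0.395) and at resolution 0.5 (0.0698). SPP1 rose in CGE or LGE interneuron-like cells (2.44 ± 0.28, adjusted p = 0.00555). With the stricter filter this call (0.267) and that of DCPS in MGE interneuron-like cells (0.653) ended, and in the fit of 10 libraries DCPS passed in none of the 7 classes.

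The vesicular glutamate transporter gene SLC17A6 fell in striatal projection neuron-like cells from 56.5 and 93.2 CPM to 6.61 and 6.29 CPM (-3.50 ± 0.35, adjusted p = 0.00468), and the zinc finger gene ZIC4 fell there as well (-2.58 ± 0.34, adjusted p = 0.0406). Without IVH K232 neither passed (adjusted p = 0.0782 and 0.307), and without IVH K231 ZIC4 did not (0.318). The highest adjusted p over the alternatives were these, and the lowest 7.56e-31 and 3.02e-23. In oligodendrocyte-like cells HMOX1 rose from 1.73 and 1.03 CPM to 14.3 and 37.9 CPM (adjusted p = 0.00342), DCPS from 0.866 and 0 CPM to 25.7 and 33.7 CPM (adjusted p = 9.87e-05) and LOC100328967 by 1.95 ± 0.32 (adjusted p = 0.00342). With DESeq2 each of the 3 stood at an adjusted p of 0.184; without IVH K232 DCPS and LOC100328967 stood at 0.999, and without IVH K231 the latter at 0.197. Over the alternatives their lowest adjusted p were 2.56e-07, 4.83e-10 and 2.52e-05 and the highest 1.00. The HMOX1 calls in endothelial-like and GE intermediate progenitor-like cells ended without IVH K232 (2.74, adjusted p = 0.0727, and 2.53, adjusted p = 0.0917), the highest values over the alternatives, and the latter also at resolution 0.5 (0.0698). In microglia-like cells, where none passed, HMOX1 went from 291 and 396 CPM to 2537 and 3151 CPM (3.26 ± 0.34). The antioxidant genes SRXN1 (3.35 ± 0.35) and GCLM (2.43 ± 0.26), the iron-binding PIR (4.80 ± 0.48) and the haem transporter SLC48A1 (2.40 ± 0.25) were also higher there in each IVH library, each at an adjusted p of 0.0566.

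No Hedgehog gene passed singly with IVH in edgeR on all 4 libraries after the filter. HHIP, a target that binds and restrains Hedgehog ligands, stood at -1.10 ± 0.31 in all cells (adjusted p = 0.603), -1.49 ± 0.34 in astroglia-like (0.314) and -1.38 ± 0.36 in cycling progenitor-like cells (0.152). It passed in all cells without no IVH K231 (adjusted p = 0.0363; up to 1.00 over the alternatives). In astroglia-like cells it passed with DESeq2 (0.0102) and with no filter on low counts, and its adjusted p went up to 1.00 under the others. The receptor gene PTCH1 stood at -0.46 ± 0.31 in all cells and -0.78 ± 0.31 in astroglia-like cells, and the transcription factor GLI1 at -0.42 ± 0.36 and -0.80 ± 0.32. Without no IVH K231 PTCH1 stood at 0.02 and -0.28, so its sign in all cells hung on that library. SHH itself had 19, 27, 17 and 12 UMIs (-0.63 ± 0.52). As a set the 20 Hedgehog pathway components fell in all cells (median -0.40, camera adjusted p = 0.00131; adjusted p = 0.336 with an estimated correlation; median -0.23 without no IVH K231), with 0 rising or falling over all genes or adjusted over the list alone. The 12 measured Hedgehog transcriptional targets fell in all cells (median -0.42, camera adjusted p = 0.00240; adjusted p = 0.336 with an estimated correlation) and in astroglia-like cells (median -0.47, camera adjusted p = 0.00730; adjusted p = 0.298 with an estimated correlation), and 1 fell in the latter adjusted over the list alone. Without no IVH K231 the target medians were -0.11 (adjusted p = 0.178; 2.11e-05 to 0.336 over the alternatives) and -0.16 (0.0946; 7.84e-05 to 0.298). Their direction was down in 13 of 13 fits, 2 of which passed.

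The MGE interneuron transcription factors did not pass in all cells (19 measured, median -0.12, camera adjusted p = 0.130) and fell in cycling progenitor-like cells (17 measured, median -0.40, camera adjusted p = 3.48e-05; adjusted p = 0.261 with an estimated correlation; median -0.15 without IVH K232), where 0 members passed even when adjusted over the list alone. Interneuron identity and migration genes did not pass in all cells (median 0.03 with a downward test, camera adjusted p = 0.710). By class that list rose in GE intermediate progenitor-like cells (10 measured, median 0.37; adjusted p = 0.453 with an estimated correlation) and fell in astroglia-like (15, -0.26; 0.298) and cycling progenitor-like cells (12, -0.36; 0.276). The GE intermediate progenitor-like class joins 2 clusters. Counted before doublets were removed, the neuron-like one has 6 and 405 cells without and 363 and 520 with IVH, and the S-phase one 336 and 278, and 272 and 364. No IVH K226 differs from the other libraries in the make-up of this class. Neuronal maturation genes fell in 4 and rose in 1 of 13 fits, and 6 members fell adjusted over the list alone. With an estimated correlation none passed (adjusted p of 0.261 or above). In all cells GAD1, the GABA-synthesising enzyme, stood at -0.02 ± 0.44, DLX1 at -0.21 ± 0.23, LHX6 at 0.40 ± 0.60 and the neuropeptide SST at 2.53 ± 1.33, none passing. These values hung on single libraries: over the alternatives GAD1 ran from -0.53 to 0.77, DLX1 from -0.45 to 0.07, LHX6 from -0.23 to 1.54 and SST from 1.15 to 4.93. LHX6 was lower without no IVH K226 and passed without no IVH K231 (adjusted p = 0.0402). Neurogenesis factors of other lineages fell in all cells (11 measured, median -0.34, camera adjusted p = 0.0344; adjusted p = 0.336 with an estimated correlation), with 0 members passing.

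Inflammatory and stress lists rose. In all cells the activated and phagocytic microglia list (13 measured, median 0.98, camera adjusted p = 5.35e-08), the inflammatory cytokines (20 measured, median 0.88, camera adjusted p = 9.32e-08) and the oxidative stress response (14 measured, median 0.71, camera adjusted p = 3.61e-05) rose, each at an adjusted p of 0.336 with an estimated correlation. Without IVH K232 the median of the last was 0.47. Microglia-like cells, which carry many of these genes, also made up more of the cells with IVH (6.23% and 9.30%), so the sums over all cells move with that share. No member passed over all genes; adjusted over the list alone, 6, 6 and 7 rose and 0, 0 and 1 fell. The oxidative stress list stood highest in microglia-like cells (13 measured, median 1.32, camera adjusted p = 3.62e-12; adjusted p = 0.305 with an estimated correlation), with 9 rising adjusted over the list alone. Homeostatic microglia genes fell in microglia-like cells (9 measured, median -0.45, camera adjusted p = 6.52e-04; adjusted p = 0.387 with an estimated correlation) and rose in all cells (10 measured, median 0.40; 0.336). Without no IVH K231 the first of these stood at -0.12 (adjusted p = 0.332; 5.45e-06 to 0.429 over the alternatives). In cycling progenitor-like cells the reactive astrocyte list (10 measured, median 0.79, camera adjusted p = 6.16e-06; adjusted p = 0.276 with an estimated correlation; median 0.40 without IVH K232) rose with CD44, and the activated microglia list (8 measured, median 0.63, camera adjusted p = 1.05e-05; adjusted p = 0.261 with an estimated correlation) with SPP1; adjusted over the list alone, 3 and 4 members rose. That last list was the only 1 of 246 tests that passed with fry (adjusted p = 0.0363). Of these 246 tests, 87 passed with camera and 0 with an estimated correlation, the smallest adjusted p there being 0.261. In the simulated data of this layout, a list with every member raised reached only 0.0428 with an estimated correlation in all cells, before adjustment. A list that falls short with an estimated correlation here is therefore not shown to be unchanged.

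Over the fits of all cells and 13 classes, haem and iron handling passed upward in 10 of 14, with 4 member calls (HMOX1 in 3 classes among them) and 31 adjusted over the list alone. In all cells that list (median 0.21, camera adjusted p = 0.00190; adjusted p = 0.336 with an estimated correlation) did not pass without no IVH K231 (adjusted p = 0.178; 2.86e-05 to 0.336 over the alternatives), and its median was 0.74 without no IVH K226. Oxidative phosphorylation passed upward in 11 of 14 fits with 0 members passing, and in all cells had a median of 0.37 (camera adjusted p = 6.61e-05; adjusted p = 0.336 with an estimated correlation). Upward and downward passes of 14 fits were 8 and 0 for oxidative stress and for activated microglia. They were 6 and 1 for reactive astrocyte, 5 and 2 for interferon response and 5 and 1 for cell cycle. Dissociation and immediate early genes had 5 and 0, hypoxia 4 and 0, p53 2 and 0, and Notch signalling 0 and 0. Inflammatory cytokines passed upward in 1 of 6 fits, and the oligodendrocyte list downward in 2 of 9. The blood list, with 3 genes measured in 1 fit, did not pass (camera adjusted p = 0.130). None of these calls held with an estimated correlation.

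The class shares differed by less than the spread or could not be resolved with 2 libraries against 2, where the smallest exact permutation p is 0.333. MGE interneuron-like cells made up 6.38% ± 3.75 of cells without and 11.2% ± 3.55 with IVH (SD, n = 2 and 2; exact permutation p = 0.667). CGE or LGE interneuron-like cells made up 19.7% ± 3.67 and 15.4% ± 0.523 without overlap (exact permutation p = 0.333), GE intermediate progenitor-like cells 7.14% ± 4.54 and 9.08% ± 0.460 (exact permutation p = 1) and cycling progenitor-like cells 8.52% ± 0.723 and 8.41% ± 0.957 (exact permutation p = 1). Microglia-like cells made up 6.23% ± 0.744 and 9.30% ± 2.52, without overlap (exact permutation p = 0.333). Choroid plexus-like cells came from no IVH K226 alone, with 591 of 8113 cells (7.29%, 95% exact interval 6.73% to 7.87%); the counts of 0 in the other libraries allow up to 0.0578%. This library also held 3.74% MGE interneuron-like cells (95% exact interval 3.33% to 4.17%) against 9.03% (8.34% to 9.76%) in no IVH K231. Without it the share of GE intermediate progenitor-like cells was lower with IVH, by -1.27 percentage points.

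**Figure D1:**
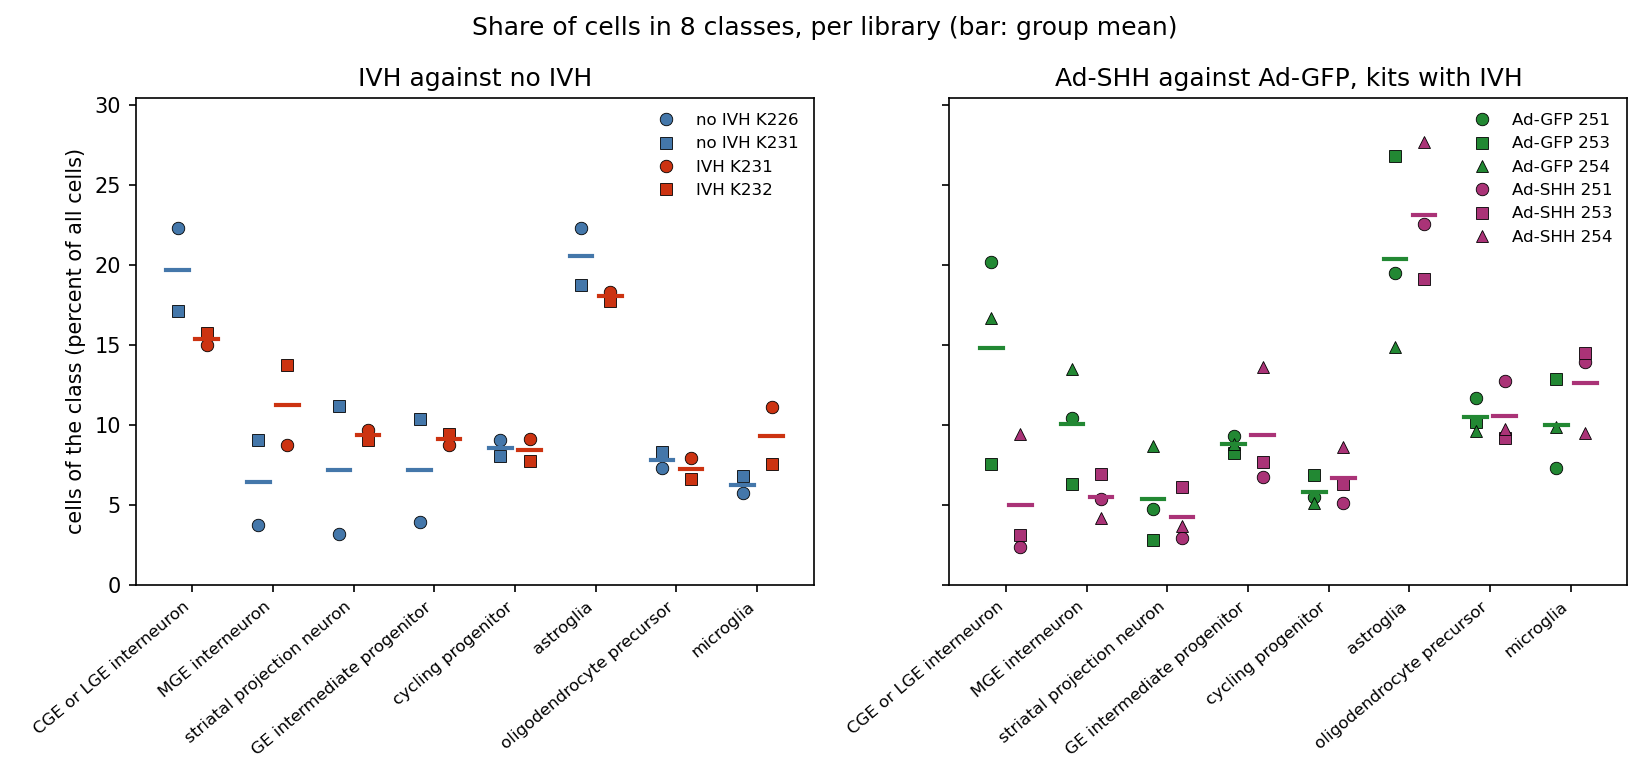
Share of cells (y axis, percent of all kept cells) in 8 cell classes (x axis), 1 point per library and a bar at the group mean, for IVH against no IVH (left) and Ad-SHH against Ad-GFP (right). CGE or LGE interneuron-like cells average 14.8% with Ad-GFP and 4.97% with Ad-SHH, and the groups overlap at 7.56% and 9.43%.

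The comparison of Ad-SHH with Ad-GFP in kits with IVH asks what added sonic hedgehog changes. PTCH1 rose from 43.5, 44.4 and 41.8 CPM with Ad-GFP to 139, 193 and 160.0 CPM with Ad-SHH in GE intermediate progenitor-like cells (1.90 ± 0.16, adjusted p = 6.43e-05). It rose likewise in cycling progenitor-like cells, from 41.7, 42.5 and 36.3 CPM to 141, 159 and 151 CPM (1.91 ± 0.13, adjusted p = 1.25e-04). HHIP rose in GE intermediate progenitor-like cells from 9.43, 5.86 and 5.37 CPM to 36.8, 57.3 and 52.6 CPM (2.77 ± 0.25, adjusted p = 1.22e-04). Both PTCH1 calls held under each of 15 alternatives, with highest adjusted p of 5.28e-04 and 0.00442. The HHIP call ended in the fit of 10 libraries (2.78, edgeR adjusted p = 0.680). The GE intermediate progenitor-like class of the Ad series joins unlike clusters, counted before doublets were removed. The larger, with NEU4, EGFR, OLIG1, DLL1 and GAS1 among its top genes, held 329, 244 and 272 cells with Ad-GFP and 291, 141 and 413 with Ad-SHH. The neuron-like other held 208, 148 and 223, and 131, 109 and 263. In which of them PTCH1 and HHIP rose was not tested. In MGE interneuron-like cells PTCH1 stood at 0.41 ± 0.29 and LHX6 at 0.02 ± 0.17 (adjusted p = 1.00 each).

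SHH RNA stood at 0.809, 0.984 and 0.540 CPM with Ad-GFP and at 12.9, 23.0 and 0.695 CPM with Ad-SHH 251, 253 and 254 (3.99 ± 1.08, adjusted p = 1.00), so the library labelled Ad-SHH 254 lay within the range of the Ad-GFP libraries. Whether these reads come from the vector or from the rabbit gene could not be looked at. Its PTCH1, HHIP and GLI1 in all cells, 108, 25.3 and 11.4 CPM, were the highest of the 6 libraries. In all cells PTCH1 (1.38 ± 0.20), HHIP (2.05 ± 0.31) and GLI1 (1.89 ± 0.40) were higher in each Ad-SHH library and did not pass (adjusted p = 1.00), nor did the cytoskeletal linker EZR (1.28 ± 0.18) and the carrier SLC25A48 (2.15 ± 0.33). In cycling progenitor-like cells HHIP stood at 2.87 ± 0.37 (adjusted p = 0.119) and, with the title number as a block, at 2.87 ± 0.31 (adjusted p = 0.0247; 1.14e-11 to 0.915 over the alternatives). Astroglia-like PTCH1 (1.68 ± 0.17, adjusted p = 0.0682) and GLI1 (2.14 ± 0.32, adjusted p = 0.229) did not pass. NKX6-2, a ventral homeodomain target, rose with the block in astroglia-like cells (2.02 ± 0.12, adjusted p = 0.0139) and GE intermediate progenitor-like cells (1.80 ± 0.16, adjusted p = 4.18e-05); without it, the adjusted p was 1.00 in both, and over the alternatives in astroglia-like cells it ran from 0.0139 to 1.00. LOC108178083 rose in GE intermediate progenitor-like cells (1.77 ± 0.25, adjusted p = 0.0197), a call that ended without Ad-GFP 253 (0.229), Ad-GFP 254 (0.106) or Ad-SHH 251 (0.0667), in a range of 1.89e-13 to 0.229 over the alternatives.

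**Figure D2:**
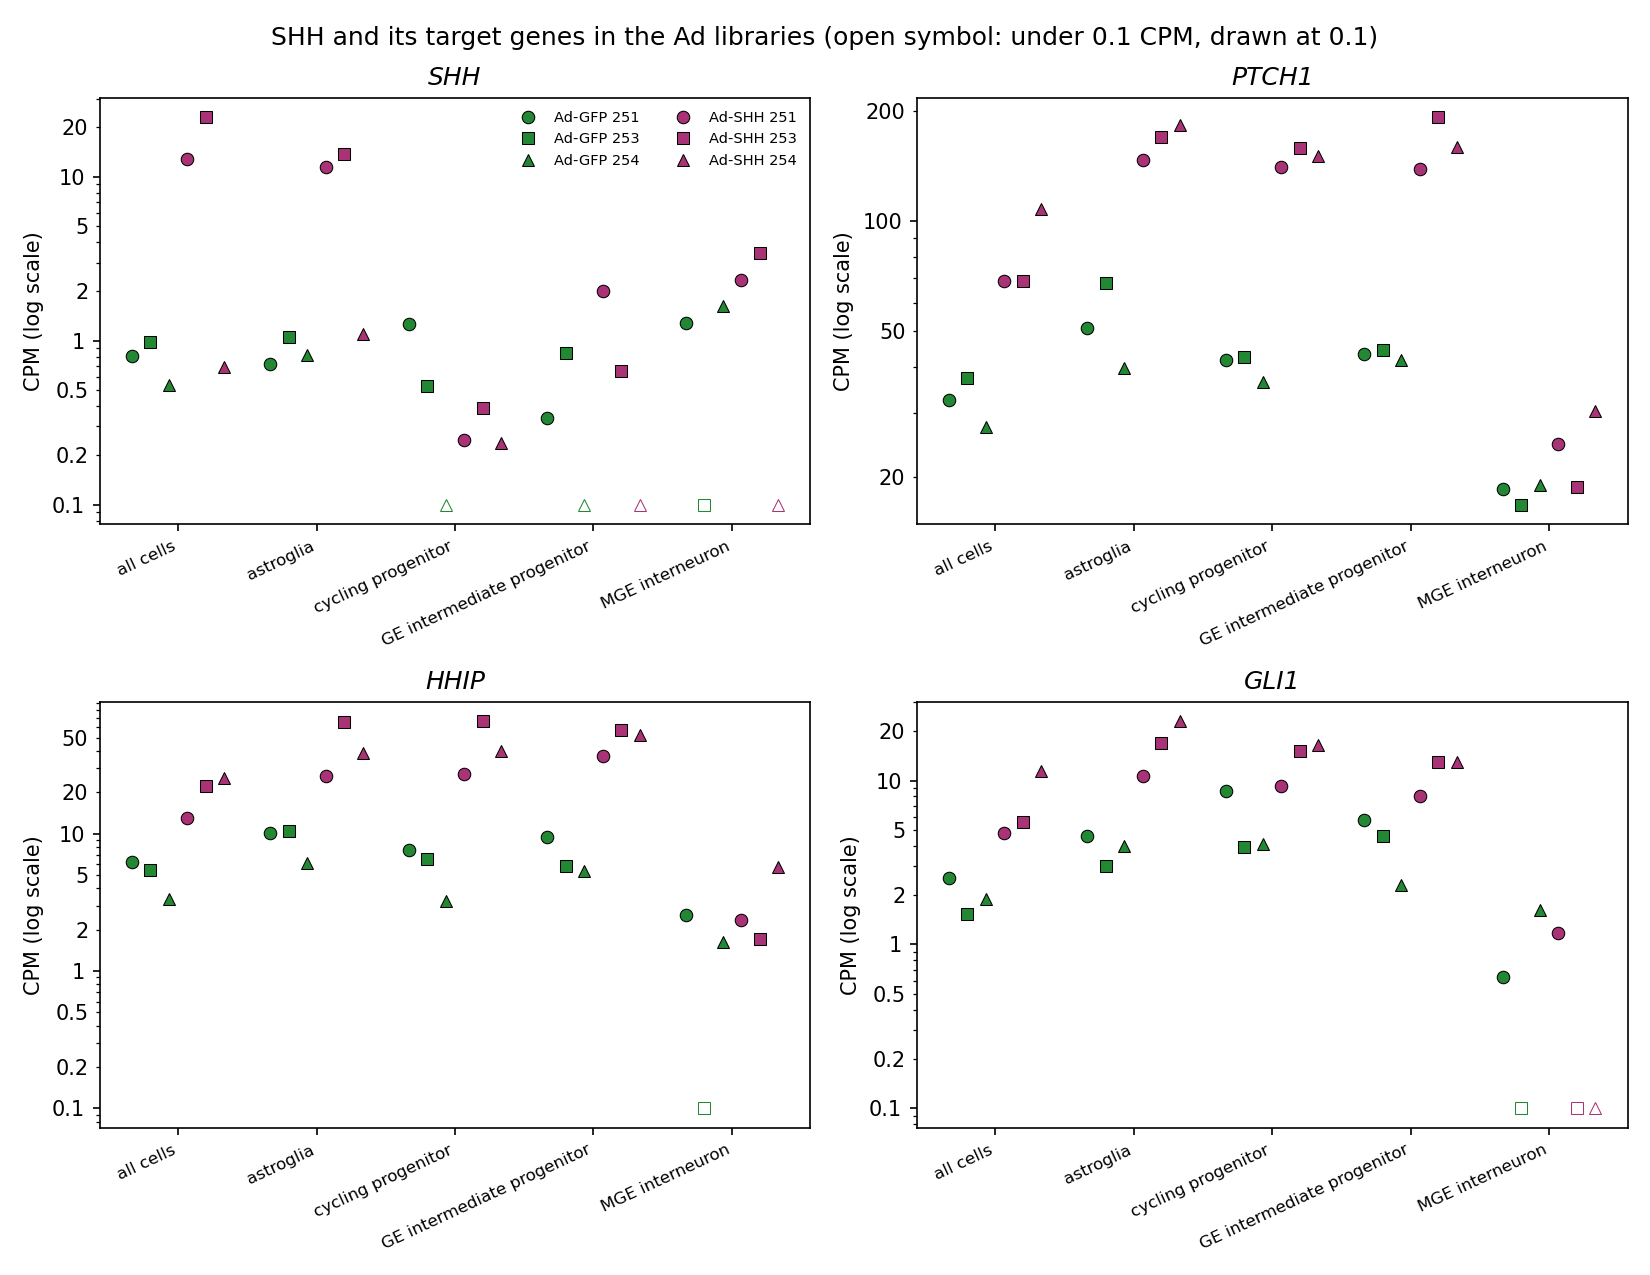
SHH, PTCH1, HHIP and GLI1 (4 panels; y axis, CPM on a log scale) in all cells and 4 classes (x axis) of the 6 Ad libraries, 1 point per library, with open symbols for values under 0.1 CPM. PTCH1 lies at 36.3 to 44.4 CPM with Ad-GFP and 139 to 193 CPM with Ad-SHH in both progenitor classes, and SHH in all cells is at 0.695 CPM in Ad-SHH 254.

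The Hedgehog transcriptional targets rose as a set in 4 of 14 fits. In GE intermediate progenitor-like cells 11 were measured (median 0.36, camera adjusted p = 2.98e-07; adjusted p = 0.179 with an estimated correlation), PTCH1 and HHIP rose and 9 did not pass; adjusted over the list alone, 3 rose and 1 fell. In cycling progenitor-like cells (median 0.40, camera adjusted p = 1.15e-07; adjusted p = 0.256 with an estimated correlation) 1 of 11 rose, and 3 adjusted over the list alone. In astroglia-like cells (12 measured, median 0.40, camera adjusted p = 1.78e-10; adjusted p = 0.237 with an estimated correlation) and all cells (13 measured, median 0.35, camera adjusted p = 9.30e-06; 0.404) 0 rose, and 6 and 4 adjusted over the list alone. Without both libraries numbered 254 the medians in all cells and GE intermediate progenitor-like cells were 0.09 and 0.14. The Hedgehog pathway components passed upward in 4 of 12 fits; in GE intermediate progenitor-like cells their median was -0.03 and their mean 0.47, with 2 of 12 rising and 10 not passing (camera adjusted p = 8.34e-04; adjusted p = 0.189 with an estimated correlation). The test of the class difference called 0 genes by limma of 7011 with Ad-SHH (392 at an unadjusted p under 0.05; 0 with the block) and 0 of 8081 with IVH (335). PTCH1, a gene named in advance, differed between MGE interneuron-like (0.41) and GE intermediate progenitor-like cells (1.90) by -1.49 ± 0.25. Its limma p was 5.39e-04 unadjusted, 7.61e-04 unadjusted with the block, and 0.824 adjusted over the 7011 genes.

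MGE interneuron transcription factors fell as a set in all cells (19 measured, median -0.31, camera adjusted p = 1.35e-05; adjusted p = 0.354 with an estimated correlation), in GE intermediate progenitor-like cells (17 measured, median -0.24, camera adjusted p = 3.66e-06; adjusted p = 0.114 with an estimated correlation) and in cycling progenitor-like cells (16 measured, median -0.43, camera adjusted p = 0.00108; adjusted p = 0.256 with an estimated correlation), and rose in oligodendrocyte-like cells (7 measured, median 0.40; 0.600). The median in all cells was -0.13 without Ad-SHH 253, and that in GE intermediate progenitor-like cells -0.15 without both libraries numbered 254. No member passed over all genes, and 1 fell in GE intermediate progenitor-like cells adjusted over the list alone. This list also holds the CGE or LGE markers NR2F1, NR2F2, SP8, SP9 and PROX1. Its fall in all cells may thus come from the lower share of CGE or LGE interneuron-like cells, which was not tested. In all cells LHX6 stood at -1.01 ± 0.36, GAD1 at -0.82, DLX1 at -0.80 and SST at -0.84 ± 1.28, none passing, beside a lower share of interneuron-like cells. Within MGE interneuron-like cells GAD1 stood at 0.04 ± 0.16 and DLX1 at 0.22 ± 0.14. With the block, DLL3, a Notch ligand of neuronal progenitors (-0.60 ± 0.11, adjusted p = 0.0465), and CRYM (-1.21 ± 0.16, adjusted p = 0.00450) fell in GE intermediate progenitor-like cells. Interneuron identity genes fell in all cells (median -0.37, camera adjusted p = 0.00728; adjusted p = 0.404 with an estimated correlation) and rose in astroglia-like cells (median 0.33; 0.237). Neuronal maturation genes fell in all cells (18 measured, median -0.26, camera adjusted p = 9.30e-06; adjusted p = 0.181 with an estimated correlation) and rose in oligodendrocyte-like cells (12 measured, median 0.33; 0.614).

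Interferon response genes fell with Ad-SHH in 13 of 14 fits. The medians were -1.42 in ependymal-like cells (17 measured, camera adjusted p = 5.88e-25; adjusted p = 0.354 with an estimated correlation), -0.84 in microglia-like (22 measured, camera adjusted p = 3.81e-22; 0.262), -0.83 in astroglia-like (23 measured, camera adjusted p = 1.04e-20; 0.237) and -0.76 in MGE interneuron-like cells (6 measured, camera adjusted p = 0.0279; 0.639). No member passed over all genes, and 23 member values fell over the 14 fits adjusted over the list alone, 12 of them in astroglia-like and 7 in ependymal-like cells. With the block IFI44 fell in ependymal-like cells (-1.59 ± 0.23, adjusted p = 0.0263; 0.226 without it and 2.08e-07 to 1.00 over the alternatives). The antiviral gene MX1 stood at 381, 504 and 336 CPM with Ad-GFP and 150.4, 175 and 387 CPM with Ad-SHH in all cells, against 67.8 to 92.2 CPM in the 4 libraries without virus. Inflammatory cytokines rose in all cells (20 measured, median 0.56, camera adjusted p = 2.86e-05; adjusted p = 0.404 with an estimated correlation), microglia-like (20 measured, median 0.47, camera adjusted p = 2.01e-06; 0.262) and cycling microglia-like cells (18 measured, median 0.71, camera adjusted p = 7.02e-14; 0.129). Microglia-like cells made up 7.29%, 12.9% and 9.86% of cells with Ad-GFP and 13.9%, 14.5% and 9.45% with Ad-SHH, so the sums over all cells move with that share. Border macrophage or monocyte-like cells made up 0.0910%, 1.23% and 0.538%, and 2.56%, 3.09% and 0.227%. The microglia-like class joins clusters parted by library, counted before doublets were removed. A cluster with IL1B among its top genes held 75, 409 and 113 cells with Ad-GFP and 515, 193 and 436 with Ad-SHH. Another, without IL1B there, held 106, 3 and 340, and 1, 0 and 1. Values of this class thus compare unlike make-ups, and how much of them this explains was not tested. With the block, 24 genes passed in cycling microglia-like cells, among them the cytokines IL1B (0.93 ± 0.10, adjusted p = 6.01e-05) and IL10 (1.54 ± 0.22, adjusted p = 0.00288), upward, and IRF7, a driver of interferon genes (-1.05 ± 0.19, adjusted p = 0.0234).

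The other calls without a block lay in 3 classes. In endothelial-like cells VTN (-3.84 ± 0.57) and HIGD1B (-3.76 ± 0.56), both markers of pericytes, fell (adjusted p = 0.0171 each). Both calls ended with doublets kept (adjusted p = 0.0820 and 0.329). They also ended without Ad-GFP 254 (0.0640 each), Ad-SHH 251 (0.0952 each), Ad-SHH 253 (0.0606 and 0.105) or Ad-SHH 254 (0.0673 and 0.121), and over the alternatives the lowest adjusted p was 4.72e-09 and 1.69e-09 and the highest 1.00. In ependymal-like cells the microfibril protein MFAP5 fell (-1.70 ± 0.24, adjusted p = 0.0460), a call that ended without Ad-GFP 251 (0.158), 253 (0.202) or 254 (0.0867), or Ad-SHH 251 (0.694) or 253 (0.116), in a range of 5.75e-09 to 0.694. In oligodendrocyte-like cells the guanine exchange factor DOCK9 fell from 118, 130.4 and 123 CPM to 42.6, 35.7 and 44.4 CPM (-1.60 ± 0.19, adjusted p = 0.0123). It did not pass without Ad-GFP 254 (0.0581), Ad-SHH 251 (0.202), 253 (0.0504) or 254 (0.0703), in a range of 2.84e-08 to 0.693. The oligodendrocyte list fell in these cells (15 measured, median -0.34, camera adjusted p = 1.16e-04; adjusted p = 0.319 with an estimated correlation), with 4 members falling adjusted over the list alone, and in oligodendrocyte precursor-like cells (10 measured, median -0.34; 0.274). The myelin genes MBP (-1.47 ± 0.14, adjusted p = 1.76e-04), MAG (-1.02 ± 0.13, adjusted p = 0.00179) and MOG (-1.27 ± 0.18, adjusted p = 0.00216) fell with the block. Without it, their adjusted p were 0.0987, 1.00 and 0.197, and over the alternatives the highest were 0.881 for MBP and 1.00 for the others. The share of oligodendrocyte-like cells was higher with Ad-SHH within each title number. It stood at 1.675%, 2.102% and 0.760% in Ad-GFP 251, 253 and 254 and at 5.841%, 3.555% and 1.279% with Ad-SHH, and the groups overlapped.

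In all, edgeR called 8 gene changes over 13 classes, 4 higher and 4 lower, against 147 with the block (68 higher and 79 lower). Leaving out Ad-GFP 251, 253 or 254 gave 22, 203 or 3 calls, and Ad-SHH 251, 253 or 254 gave 5, 7 or 102. In all cells edgeR called 0 of 15202 genes, with 446 at an unadjusted p under 0.05, 22 called by DESeq2, 1 with the block and 14 without Ad-SHH 254. The gene called with the block was TTR, the main secreted product of choroid plexus (4.34 ± 0.15, adjusted p = 0.0327; up to 1.00 over the alternatives), at 272, 493 and 1.77 CPM with Ad-GFP and 4738, 11512 and 33.2 CPM with Ad-SHH. Choroid plexus-like cells numbered 0, 1 and 0, and 170, 99 and 3, in these libraries, and without them TTR, fitted with no block, stood at 0.10 instead of 4.48. In 8 classes edgeR called 0 genes. Unadjusted p under 0.05 numbered 435 in astroglia-like, 159 in CGE or LGE interneuron-like, 158 in cycling microglia-like, 102 in cycling oligodendrocyte precursor-like, 132 in MGE interneuron-like, 108 in microglia-like, 182 in oligodendrocyte precursor-like and 101 in striatal projection neuron-like cells. DESeq2 called 39, 0, 3, 0, 0, 4, 0 and 0 genes there, and edgeR with the block 1, 1, 24, 1, 0, 0, 13 and 0. Of 272 list tests 49 passed with camera, 61 with the block, 0 with an estimated correlation and 0 with fry; the smallest adjusted p with an estimated correlation was 0.114.

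Upward and downward passes of 14 fits were 2 and 2 for dissociation and immediate early genes. They were 2 and 0 for cell cycle and for reactive astrocyte, and 1 and 1 for hypoxia. Haem and iron handling, oxidative stress and Notch signalling had 1 and 0 each. Oxidative phosphorylation, p53 and activated microglia had 0 and 0 each. Homeostatic microglia genes passed downward in 1 of 13 fits, and neurogenesis factors of other lineages in 0 of 8. The blood list passed upward in all cells, with 5 genes measured, a median of 2.06 and 0 members passing (camera adjusted p = 8.92e-04; adjusted p = 0.404 with an estimated correlation). None of these lists passed with an estimated correlation.

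With Ad-SHH the CGE or LGE interneuron-like share averaged 4.97% ± 3.88 against 14.8% ± 6.52 with Ad-GFP (SD, n = 3 and 3; exact permutation p = 0.2), and the MGE interneuron-like share 5.47% ± 1.38 against 10.1% ± 3.63 (exact permutation p = 0.2). Both pairs of groups overlapped. Within the title numbers 251, 253 and 254 the CGE or LGE interneuron-like share went from 20.2% to 2.35%, 7.56% to 3.12% and 16.7% to 9.43%, lower in each pair. The MGE interneuron-like share was lower in the pairs 251 and 254 and higher in the pair 253. Among the 5 neuron and progenitor classes alone, the MGE interneuron-like share was lower with Ad-SHH in the pair 254 only. There it went from 20.8% to 23.9% (251), 19.8% to 22.9% (253) and 25.6% to 10.5% (254). The oligodendrocyte-like share was higher in each pair, as given above. GE intermediate progenitor-like cells made up 9.34% ± 3.72 and 8.77% ± 0.536 (exact permutation p = 1) and cycling progenitor-like cells 6.65% ± 1.78 and 5.80% ± 0.907 (exact permutation p = 0.7). Among the 5 neuron and progenitor classes these 2 were higher with Ad-SHH by 9.62 and 7.71 percentage points, with overlap, while CGE or LGE interneuron-like cells were lower by 17.0. Choroid plexus-like cells numbered 170, 99 and 3 with Ad-SHH and 0, 1 and 0 with Ad-GFP, and ependymal-like cells made up 2.21% ± 1.07 and 1.24% ± 0.165; neither overlapped (exact permutation p = 0.1 each, the smallest this design allows). Chance gives such a parting in 10% of classes, and 2 of the classes showed it. The adjusted permutation p were 0.713 or above. With exchange only within the pairs of a title number, the adjusted exact permutation p were 0.95 or above.

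The last question is whether the genes changed by IVH go the other way with Ad-SHH. The 52 genes raised by IVH in cycling progenitor-like cells were higher, not lower, with Ad-SHH (median 0.17, camera p = 0.00546, adjusted p = 0.0218; adjusted p = 0.495 with an estimated correlation), and 14 of them (26.9%) had the opposite sign. In astroglia-like cells 5 of 10 had the opposite sign (adjusted p = 0.877), in ependymal-like cells 8 of 10 (adjusted p = 0.156) and in GE intermediate progenitor-like cells 5 of 5 (adjusted p = 0.215). No single gene of these sets passed with Ad-SHH. The GE intermediate progenitor-like class differed in make-up between the series. In the Ad libraries it held a cluster marked by NEU4, OLIG1, GAS1 and EGFR, and a cluster marked by these genes was left unnamed in the IVH series. Of the sets of 100 genes with the smallest p, 5 of 26 passed with camera and 0 with an estimated correlation (adjusted p of 0.600 or above). The genes lower in all cells (70 of 94 of opposite sign, camera adjusted p = 6.59e-04) and higher in ependymal-like cells (59 of 96, camera adjusted p = 0.0413) went the other way. Choroid plexus-like cells stood in no IVH K226 but not with IVH, and mainly in Ad-SHH 251 and 253 among the Ad libraries, so their genes go the other way in all cells by make-up alone. How much of the set this explains was not tested. Those lower in cycling progenitor-like cells (28 of 95, camera adjusted p = 0.00570) and higher (36 of 96, 0.0413) and lower (31 of 96, 6.00e-07) in oligodendrocyte-like cells went the same way. With the block 8 passed with camera and 0 with an estimated correlation. The added ones were those lower in astroglia-like (68 of 97 of opposite sign) and GE intermediate progenitor-like cells (55 of 96), which went the other way, and those higher in cycling progenitor-like cells (28 of 99), which went the same way, each at a camera adjusted p of 0.0153. HMOX1 stood at 529 to 1336 CPM and PSMB9 at 55.1 to 85.8 CPM in all cells of the 6 Ad libraries, beside 549.9 and 839 CPM and 42.8 and 47.2 CPM in the IVH libraries. GFAP stood at 284 to 419 CPM with virus and at 125 and 179 CPM with IVH alone.

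**Figure D3:**
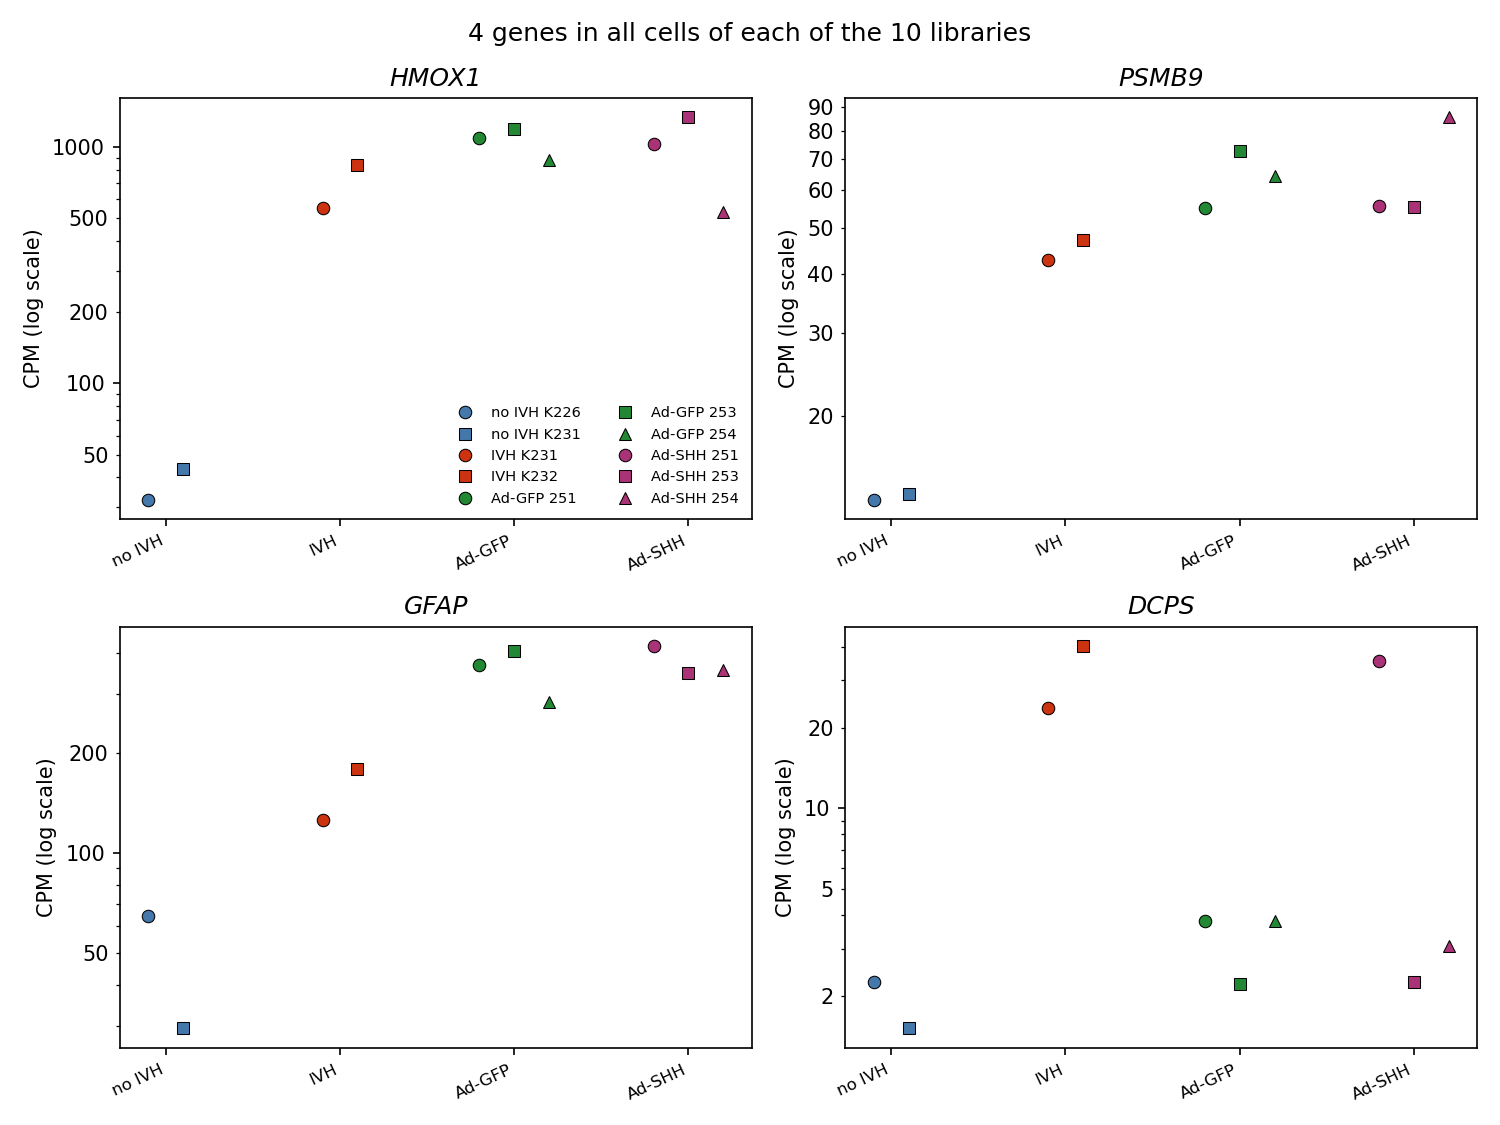
HMOX1, PSMB9, GFAP and DCPS (4 panels; y axis, CPM on a log scale) in all cells of the 10 libraries by group (x axis), 1 point per library. HMOX1 is at 32.2 and 43.4 CPM without IVH and at 529 CPM or more in each other library, and DCPS is at 35.4 CPM in Ad-SHH 251 but at 2.22 to 3.81 CPM in the other Ad libraries.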

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

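All tests in this part were chosen after the results they bear on were seen. The Ad libraries also carry counts of multiplexing tags, short barcodes that mark the cells of 1 sample, which entered no comparison above. The share of tag counts outside the leading tag was 8.78%, 6.01% and 10.2% in Ad-GFP 251, 253 and 254, and 52.8%, 5.59% and 4.56% in Ad-SHH 251, 253 and 254. Ad-SHH 251 thus held 2 tags at similar counts, CMO301 with 19054800 and CMO311 with 18340807, and the second made up 45.4% of its tag counts. In Ad-GFP 251 CMO311 was also the second tag, with 1417967 counts. In the 4 libraries numbered 253 and 254 the second tag was the leading tag of the library with the same number and the other virus. Whether Ad-SHH 251 holds cells of more than 1 kit cannot be read from the labels, and no value above was corrected for it.

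Several genes were higher with IVH in unlike cell classes at once, among them SPP1, HMOX1, PSMB9 and DCPS, and a candidate explanation is RNA that leaked from microglia-like cells into other droplets. From the level of 8 other microglial genes in each of 12 other classes, SPP1 and AIF1 stood at a mean log2 of -0.43 (SD 0.91) relative to the level such leakage would give in the IVH library nearer 0, and -0.46 (SD 0.61) in the other. The rise of SPP1 in interneuron-like and progenitor-like cells is thus consistent with free RNA. In cycling progenitor-like cells SPP1 stood at -0.99 and -1.04 and AIF1 at -0.13 and 0.13, so the rise of the activated microglia list there, the 1 pass with fry, may be free RNA as well. PSMB9 and DCPS stood at 8.30 (SD 2.41) and 8.68 (SD 2.56), far more RNA than leakage from microglia-like cells would bring, which argues against it for both. HMOX1 stood at 1.48 (SD 1.06) and 2.15 (SD 1.38), so that over the classes as a whole leakage and a rise within them cannot be told apart, because the excess lies within its spread of a 4-fold margin. The mean covers unlike classes: endothelial-like cells stood at 3.26 and 3.64, with 45.7 and 87.1 CPM where leakage would bring 4.75 and 6.97, and astroglia-like cells at 3.07 and 4.62. GE intermediate progenitor-like cells, where HMOX1 was called as well, stood at 1.26 and 2.12, with 25.8 and 47.5 CPM where leakage would bring 10.8 and 10.9, and CGE or LGE interneuron-like cells at -0.42 and 0.21. Leakage from astroglia-like cells was not tested, so the rise of GFAP in GE intermediate progenitor-like cells may be free RNA too.

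For DCPS a variant or other difference between kits may explain the rise. It was low, under 0.25 times the lower IVH library, in 5 of the 6 Ad libraries, though all came from kits with IVH, and high in Ad-SHH 251 at 35.4 CPM. The day of the Ad libraries is not given, so a rise that passes with time stays open, as do the other biological differences between the kits, which the design does not name and which were not tested. For PSMB9 no technical explanation besides leakage was tested.

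The library labelled Ad-SHH 254 held SHH RNA within the range of the Ad-GFP libraries and the highest PTCH1, HHIP and GLI1. A wrong label is argued against, since these genes stood 2.90, 4.09 and 4.50 times above the highest Ad-GFP library, where the Ad-GFP libraries differed among themselves by 1.36, 1.86 and 1.65 times. Its classes, at the lower SHH level of the same class in the other 2 Ad-SHH libraries, would bring 249.7 UMIs of SHH, and 26 were seen, 10.4% (95% counting interval 6.80% to 15.3%). This argues only against fewer cells of the SHH-rich classes at an unchanged level in each class. Fewer SHH-bearing cells within each class, or a loss of SHH RNA by the time of sampling with target RNA still high, may explain it; both stay open and were not tested.

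CGE or LGE interneuron-like cells were fewer with Ad-SHH, and a candidate explanation is dilution by glial, choroid plexus-like or other cells taken along in the dissection. Among the 5 neuron and progenitor classes alone their share was still lower, by -17.0 percentage points, or -2.13 SD within groups. Within the title numbers 251, 253 and 254 it went from 40.3% to 10.5%, from 23.9% to 10.4% and from 31.7% to 23.9%, lower in each pair. Cells outside these 5 classes cannot alter this share, so dilution by them does not account for the difference within the 5. The libraries of the 2 groups overlapped and 3 pairs allow no exact permutation p under 0.25. A chance difference between libraries and a loss of these neurons therefore cannot be told apart. How much of the lower share among all cells is dilution cannot be told either. The place of the dissection along the ganglionic eminence is not given for each library, and its part was not tested.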

How the results depend on the processing

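Alternatives chosen after seeing the data were the removal of both libraries numbered 254, sums without choroid plexus-like cells, shares among the 5 neuron and progenitor classes, the block in the class difference, and the tests with an estimated correlation and with fry for the IVH gene sets. None of the calls reversed. In all cells with IVH, where edgeR called 0 genes (1018 at an unadjusted p under 0.05), DESeq2 called 209, no filter on low counts 1, the fit of 10 libraries 1, sums without choroid plexus-like cells 2, and the removal of 1 library 0 to 809. Summed over classes the 91 calls became 223 with DESeq2, 691 with no filter, 57 with the fit of 10 libraries, 75 with doublets kept and 125 with the stricter cell filter, and ran from 81 (without IVH K232) to 2190 (without no IVH K231) with 1 library left out. In such fits the spread is pooled, and the lone library of a group is assumed to vary like the other group. Calls of named genes were counted once per class, so a gene called in several classes counts several times. Of 27 such calls with IVH, 23 were lost under at least 1 alternative, 12 of them with a library left out and 17 in the fit of 10 libraries. The 4 that held were PSMB9 and FOSB in cycling progenitor-like and HOPX and PSMB9 in ependymal-like cells. With Ad-SHH the 0 calls in all cells (edgeR, 446 at an unadjusted p under 0.05) became 22 with DESeq2, 1 with the block and 0 to 14 with 1 library left out. The 8 calls over classes became 81 with DESeq2, 184 with no filter, 147 with the title number as a block, 107 without both libraries numbered 254, 13 with the stricter cell filter and 5 with the fit of 10 libraries, and ran from 3 (without Ad-GFP 254) to 203 (without Ad-GFP 253). Of 8 such calls of named genes, 6 were lost somewhere, and those of PTCH1 in the 2 progenitor classes held. Of the IVH list tests, 87 passed with camera, 0 with an estimated correlation, 1 with fry and 65 to 93 with 1 library left out; with Ad-SHH the numbers were 49, 0, 0 and 48 to 70, and 61 with the block. Shares had no call, so a change of sign was counted as a moved value. The GE intermediate progenitor-like share moved to -1.27 without no IVH K226 (up to 5.15 with another library left out), and with Ad-SHH to -1.57 without Ad-SHH 254 (up to 1.86). At resolution 0.5 it moved to -10.2 with Ad-SHH, where the CGE or LGE interneuron-like cells join this class and give no value of their own. The cycling progenitor-like share moved with IVH to 2.40 with the stricter filter, and ran from -0.792 (without IVH K231) to 0.562 (without IVH K232) through 0.396 (without no IVH K226), and with Ad-SHH from -0.124 (without Ad-SHH 254) to 1.62. With 1 library left out the MGE interneuron-like difference kept its sign, at 2.17 to 7.47 with IVH and -6.49 to -2.87 with Ad-SHH, as did the CGE or LGE interneuron-like one, at -6.93 to -1.73 and -13.5 to -7.15. Among the 5 neuron and progenitor classes they were 8.28 and -2.93, and -12.99 and -17.0. Of the IVH gene sets 1 passed with Ad-SHH, 5 as sets of the 100 smallest p (8 with the block), 0 with an estimated correlation, 0 with fry and 1 with the block. The class difference had 0 genes by limma under each alternative (327 to 392 at an unadjusted p under 0.05, smallest adjusted p 0.824). The block left the share differences as they were. It gave 75 calls in oligodendrocyte-like (1 without it), 15 in cycling progenitor-like (1), 9 in GE intermediate progenitor-like (3), 6 in endothelial-like (2) and 2 in ependymal-like cells (1). Counts in single classes moved upward 67 and downward 16 times with IVH, and 55 and 20 times with Ad-SHH. Of values of single genes 518 stayed, 51 passed newly, 48 no longer passed and 21 moved with IVH, against 487, 40, 31 and 15 with Ad-SHH. Lists stayed in 45 and fell short in 27 cases with IVH, and in 88 and 22 with Ad-SHH, and shares of other classes moved in 4 cases and stayed in 36 with IVH, against 2 and 53. Under the stricter filter 8 and 7 of the 13 classes were left to test although the sums rose, and the cause was not tested for any setting.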

Other observations

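Of the tests in this part, those over other splits of the libraries were chosen after the results were seen, except for the IVH gene sets and the class difference. In Ad-SHH 251 and 253 SHH RNA lay mostly in cells that line the ventricle, and in Ad-SHH 254 astroglia-like cells held 14 of its 26 UMIs. Choroid plexus-like cells of Ad-SHH 251, 253 and 254 held 307, 608 and 5 UMIs of SHH (116, 287 and 147 CPM), ependymal-like cells 185, 74 and 4 (76.6, 112 and 4.15 CPM) and astroglia-like cells 177, 105 and 14 (11.5, 13.8 and 1.09 CPM). GE intermediate progenitor-like cells, in which PTCH1 and HHIP rose, held 5, 1 and 0 UMIs, and cycling progenitor-like cells 1 in each library.

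With the title number as a block, edgeR called 13 genes in oligodendrocyte precursor-like cells, 1 higher and 12 lower (n = 3 and 3). Without the block it called 0 (182 at an unadjusted p under 0.05), as did DESeq2. This class joins clusters parted by library, counted before doublets were removed. The first held 638, 11 and 516 cells of Ad-GFP 251, 253 and 254, and 3, 2 and 43 of Ad-SHH. The second held 40, 465 and 21, and 791, 302 and 456. The calls thus compare unlike make-ups of the class, and how much of them this explains was not tested. UST, a sulfotransferase of glycosaminoglycans (-1.14 ± 0.18, adjusted p = 6.85e-04) and PHGDH, the first enzyme of serine synthesis (-0.64 ± 0.11, adjusted p = 0.00121), fell, and the Notch effector HES1 rose (0.50 ± 0.10, adjusted p = 0.0246). In cycling microglia-like cells the scavenger receptor CD36 (1.67 ± 0.16, adjusted p = 8.50e-06) and the cytoskeletal PLEK (1.14 ± 0.10, adjusted p = 8.50e-06) rose, and RNASE4 fell (-1.11 ± 0.18, adjusted p = 0.00554). In cycling progenitor-like cells, with 12 higher and 3 lower, the tetraspanin CD9 (0.76 ± 0.12, adjusted p = 0.0402) rose and C1QTNF3 fell (-2.60 ± 0.27, adjusted p = 0.00375). C1QTNF3, a secreted relative of adiponectin, also fell in GE intermediate progenitor-like cells (-2.01 ± 0.26, adjusted p = 0.0406).

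GFAP stood at 64.5 and 29.6 CPM without IVH, 125 and 179 CPM with IVH, and 284 to 419 CPM in the Ad libraries, and SPP1 at 2048 and 795 CPM, 4697 and 3521 CPM, and 439 to 8425 CPM. The Ad libraries differ from the others in virus and injection and their day is not given, so no test compares them; DCPS, at under 0.25 times the lower IVH library in 5 of the 6, shows how far kits with IVH differ. No IVH K226 stood apart in its make-up, in cells counted before doublets were removed. A cluster of 1775 CGE or LGE interneuron-like cells and a cluster of 650 choroid plexus-like cells came from it alone. It held 528 cells of an oligodendrocyte precursor-like cluster to which the other 3 libraries gave 26, 31 and 32. In the same count, a microglia-like cluster of the Ad series held 106, 3 and 340 cells of Ad-GFP 251, 253 and 254, and 1, 0 and 1 of Ad-SHH.

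The 6 Ad libraries form 10 splits of 3 against 3, too few for a share under 0.05. Of genes in all cells edgeR called 0 in the real split and at most 3 in another (10 splits with as many, the real one included); over classes it called 8, at most 774 in another (7 splits). Lists numbered 49, at most 89 (6 splits), IVH gene sets 1, at most 3 (6 splits), and genes of the class difference 0, at most 0 (10 splits). By class the calls were 1, at most 460, in cycling progenitor-like cells (6 splits), 2, at most 8, in endothelial-like (6 splits) and 1, at most 8, in ependymal-like (8 splits). They were 3, at most 24, in GE intermediate progenitor-like (5 splits) and 1, at most 160, in oligodendrocyte-like cells (5 splits). The other splits that part all 3 pairs of title numbers gave 0, 0 and 0 calls in cycling progenitor-like and in oligodendrocyte-like cells. They gave 0, 0 and 1 in GE intermediate progenitor-like and in endothelial-like cells, and 1, 0 and 1 in ependymal-like cells. Such splits are too few for a test. The split of Ad-GFP 251, Ad-GFP 254 and Ad-SHH 254 against the others, with 774 calls, points to a structure of the samples other than the virus. Like the 5 others that part 1 pair of title numbers, with 9 to 75 calls, it sets whole pairs against each other. The splits that part all 3 pairs, as the real one does, gave 1, 0 and 6 calls against 8. Their lists numbered 42, 32 and 32 against 49, and their calls with the block 111, 35 and 24 against 147. By class, the block gave 0, 0 and 0 calls against 75 in oligodendrocyte-like and 0, 0 and 0 against 15 in cycling progenitor-like cells. Cycling microglia-like, GE intermediate progenitor-like and oligodendrocyte precursor-like cells also had most calls in the real split. Another split had more in endothelial-like (67 against 6), ependymal-like (16 against 2), microglia-like, cycling oligodendrocyte precursor-like, interneuron-like and striatal projection neuron-like cells.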
